A study of Danio rerio with 8 samples.

How the data were processed

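Total RNA from 8 pools of whole zebrafish larvae, 4 control and 4 LIS1 morphant, was labelled with Cy3 and hybridised to 1-colour arrays, per the labels. The labelling protocol in the labels names mouse arrays, whereas the file headers and probe names are those of a zebrafish design, Agilent number 026437, with the genome assembly danRer6. The scanner files hold intensity values made with Feature Extraction 10.7.3.1, per the file headers: a processed signal, from which background had been subtracted, and raw median spot and background signals. None of these had been normalized between arrays. The deposited value table holds log2 values. No source used here states how the authors made them, but each column ranked the probes like the log2 median signal of a scanner file (Spearman above 0.999), all columns had nearly the same distribution, and column medians lay between 8.127 and 8.131. However, 6 of the 8 columns matched the scanner file of another sample of the same group, in the same order in both groups. Control columns 2, 3 and 4 matched control files 4, 2 and 3, and the morphant columns likewise. Group membership is not touched by this, and which of the names is right is open. The match shows log2 levels without centring by gene, which have no direction to settle.

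Analyses started from the scanner files. The processed signal was taken to log2 and each array's 75th percentile was subtracted. Control spots and spots marked as outliers were left out, leaving 43803 spots and 43603 probes per array, and spots of a probe were averaged. A probe was kept if it was well above background on all 4 arrays of at least 1 group, which held for 36707. Files held no gene names, so probes were named through their accession, without versions, in a RefSeq gene table of the assembly GRCz12tu. That table served only for names and for gene order. A match was found for 25069 probes, to 12858 symbols, and the other 18534 kept the file's identifier. Of several probes of a gene, the probe with the highest mean over all 8 arrays stood for it. This left 23400 genes, 12142 with a symbol, of which 40 lacked a value on an array.

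Groups were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Unless said otherwise, adjusted p-values of genes come from this fit, changes are morphant minus control on the log2 scale, and standard errors are moderated. Where a probe was not well above background on any array of a group, its fold is given as at least N-fold. For it the bright group's mean was set against the dim group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background. No member of the gene lists needed such a bound. The 26 gene lists were written from textbook knowledge before the data were examined and tested with camera (preset correlation 0.01), with Benjamini-Hochberg adjustment over the lists, with camera using an estimated correlation and with fry beside it. They cover dynein and LIS1 partners, neuronal migration, GABA signalling, glutamate signalling, synaptic vesicle machinery, voltage-gated ion channels, immediate early genes, phototransduction, lens, neural progenitor and glia, oligodendrocyte and myelin, cell cycle, interferon response, leukocyte and inflammation, heat shock and unfolded protein, skeletal muscle, heart, liver, exocrine pancreas, intestine, erythroid, cartilage and bone, pigment cell, hatching gland, and epidermis and ionocyte. A further list and some genes are not reported here. Some genes, 23 in all, stand on more than 1 list.

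Genes named in the text follow a rule set before the data were examined. It takes every probe of pafah1b1a and pafah1b1b, the 12 named genes with the largest rise and the 12 with the largest fall among those past the threshold whose groups do not overlap, and up to 2 members per list and direction that passed. Clone-named and unnamed genes were left out of it. Numbers for single measures of the arrays were compared with two-sided exact permutation tests, for which 4 against 4 allows no p below 0.0286. The labels describe the replicates as separate pools of larvae.

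Replicate numbers occur in both groups, and a control and a morphant array of a number shared a slide and a scan, per the file headers. Deviations from the group means correlated between arrays of the same number at 0.454, 0.159, 0.322 and 0.283, so the numbers were taken to pair the samples, and 7 of 8 arrays had their best partner under their own number. Slide, scan and replicate number are therefore a single block here. A fit with this block was run beside the fit without it. It is given beside a result where it changed the call or the count by over 1.5 times. No 2 arrays held identical values, and arrays of a group correlated at 0.976 to 0.993.

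The test was tried on simulated data with the real genes' means and spreads, for the comparison of LIS1 morphants with controls over 23360 genes. Of 50 changed genes per size, 6% were called at a log2 change of 0.5, 56% at 1, 94% at 2 and 96% at 3. There were 13 false calls, and none was called when nothing was changed. In the real data 38.3% of the tested genes passed. With far fewer changed genes the adjustment is stricter, so the simulated shares do not give the sensitivity in the real data. A simulated list of 40 genes shifted by 0.5 gave a camera p of 1.39e-36, and 40 unshifted genes gave 0.996. The simulated genes were drawn independently of each other, whereas the correlations estimated for the 9 lists that passed ran from 0.133 to 0.5. The simulation therefore does not check the preset correlation of 0.01. Alternatives covered quantile normalization, median scaling, normexp background correction with an offset of 50 (on the median signal, since the files hold no mean signal), the deposited values, other background filters, other rules for several probes, the replicate block as a fixed and as a random effect, an intensity trend with robust spread, array weights, other thresholds, other list tests and leaving out each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.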

Results

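Gene expression was measured in whole zebrafish larvae at 4 days post fertilization, in larvae in which LIS1 had been knocked down transiently with a morpholino and in control larvae. LIS1, encoded in zebrafish by pafah1b1a and pafah1b1b, is a regulator of the microtubule motor dynein that is needed for neurons to migrate. There were 4 control samples and 4 LIS1 morphant samples, each a pool of 10 larvae of the WIK background, and each was hybridised to its own 1-colour array. Morphants had been picked for a slight phenotype and for seizure behaviour, and per the design text both groups came from shared pools of eggs. The labels do not say whether the controls were injected. The share of spots well above background lay between 83.8% and 88.8% per array, and no spot was saturated. The 75th percentile of the processed signal averaged 1237 ± 178 (SD, n = 4) on the control arrays and 1598 ± 154 (SD, n = 4) on the morphant arrays, with p = 0.0571 in a two-sided exact permutation test. The median signal of the spike-in probes went the other way, at 2503 ± 287 and 1960 ± 173 (SD, n = 4 each; exact permutation p = 0.0571). Expression levels below are log2 signals relative to the 75th percentile of the same array. Rises, falls and list medians are thus relative to that percentile, and no alternative scaled the arrays to the spike-ins. The number of arrays, 4 per group, limits the precision.

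The transcript level of the knocked-down genes was compared between the groups before any other gene. The brighter probe of pafah1b1a read 2.499 ± 0.32 (SD, n = 4) in controls and 2.57 ± 0.24 (SD, n = 4) in morphants, a difference of 0.07 with a standard error of 0.19 (limma adjusted p = 0.792). The second probe of that gene was higher in morphants, at 0.86 ± 0.27 (SD, n = 4) against 0.21 ± 0.32 (SD, n = 4), a rise of 0.65 with a standard error of 0.20 (adjusted p = 0.0305 over all probes). The 4 probes of pafah1b1b differed by -0.03 to 0.07 between the groups, each less than the spread between pools. For the brightest of them the 95% confidence interval of the difference ran from -0.69 to 0.63. The labels do not say whether the morpholino acts on translation or on splicing, so the transcript level checks neither the knockdown nor the sample labels.

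**Figure D1:**
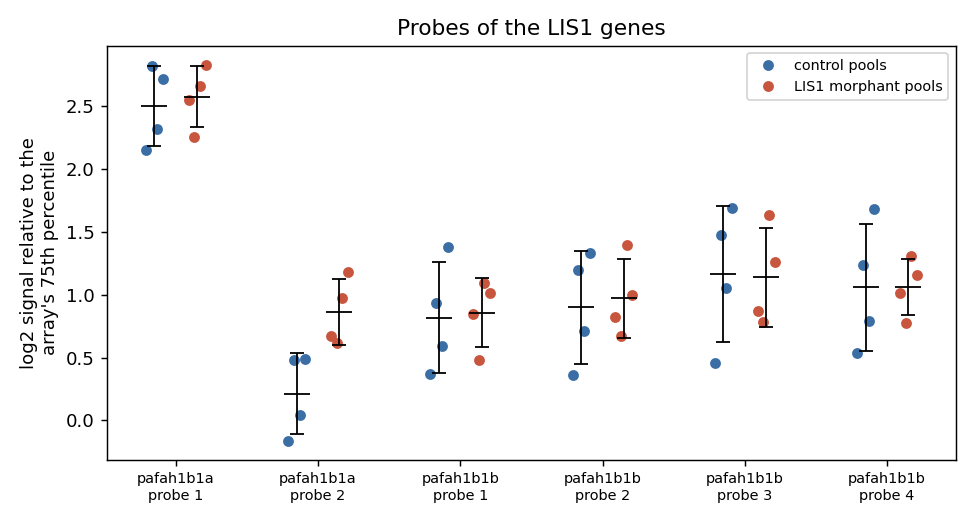
Each point is the log2 signal of a probe of pafah1b1a or pafah1b1b on an array, relative to the array's 75th percentile, for the 4 control pools and the 4 LIS1 morphant pools; bars give the mean and SD of each group. The second pafah1b1a probe is higher in morphants (0.86 against 0.21) and the other 5 probes overlap.

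Across the transcriptome, the question was which genes differed between LIS1 morphants and controls. Of 23400 genes tested, 8963 passed an adjusted p of 0.05 in the limma fit, 3848 of them higher and 5115 lower in morphants. Of these, 3806 changed by at least 2-fold, 1494 upward and 2312 downward, and 371 changed by at least 8-fold. The change had the same sign on all 4 slides, each of which carried a control and a morphant array, for 98.2% of the called genes and for 62.2% of all tested genes. The groups did not overlap for 38.1% of all tested genes, where chance gives 2.86%. The count depended on how background and scale were handled. It was 2735 when normexp background correction was followed by 75th percentile scaling, against 8582 when normexp was followed by quantile normalization, and 14119 when each of 36706 probes was tested by itself. The share of called genes that were lower was 57.1%, and 49.6% when arrays were scaled to their median.

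Genes of neuronal signalling were lower in the morphants. Among 20 measured genes of GABA signalling, the main inhibitory system of the brain, 9 fell and none rose (9 adjusted over the list alone), with a median log2 change of -0.51. The list passed camera, which compares a list with all other genes, at an adjusted p = 0.00225 with the preset correlation and not with an estimated correlation (adjusted p = 0.706). The vesicular GABA transporter gene slc32a1 fell by 1.22 (adjusted p = 0.00343), the largest change of its 4 probes. The others were at -0.7486, -0.6341 and, without passing, -0.38. The least changed probe was the brightest, and so stood for the gene, without control replicate 1, where it passed (-0.5016, adjusted p = 0.03461). It also stood for the gene without control replicate 2 (-0.3482, adjusted p = 0.205) or control replicate 4 (-0.3451, adjusted p = 0.1792). The probe reported here changed by -1.129 and -1.055 without control replicate 2 and control replicate 4 and passed. The list's median was -0.339 and -0.3364 without these arrays, and -0.4499 and -0.4902 with the probes of each gene kept as they were. Of 31 genes of glutamate signalling, 17 fell and 3 rose (18 and 3 adjusted over the list alone), with a median of -0.70 (camera adjusted p = 0.0042, and 0.706 as the adjusted p with an estimated correlation). They included glsa, a glutaminase gene that fell by 1.77, and grin2bb, an NMDA receptor subunit gene that fell by 1.76. Their standard errors were 0.25 and 0.22, and their adjusted p-values were 0.00109 and 0.000595. The vesicular glutamate transporter gene slc17a6a rose by 0.57 (adjusted p = 0.0123).

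Voltage-gated ion channel genes moved the same way, with 15 of 33 lower and 1 higher (16 and 2 adjusted over the list alone) and a median of -0.62 (camera adjusted p = 0.00225, and adjusted p = 0.706 with an estimated correlation). The L-type calcium channel gene cacna1da fell by 2.08 with a standard error of 0.26 (adjusted p = 0.000587), and the sodium channel subunit gene scn1ba fell by 1.69 with a standard error of 0.15 (adjusted p = 0.000117). After normexp and 75th percentile scaling the glutamate and channel lists no longer passed, at adjusted p = 0.062 and 0.059, and their medians shrank to -0.2204 and -0.236. The GABA list's median was between -0.6367 and -0.3091 over the settings. Within the 4 slides the median change ran from -0.81 to -0.36 for the GABA list, from -1.09 to -0.27 for the glutamate list and from -0.90 to -0.39 for the channel list. Synaptic vesicle genes had a median of -0.19, with 14 of 38 lower and 6 higher, and did not pass (camera adjusted p = 0.267). With every probe tested the list passed at a median of -0.3082, but there each probe of a gene counted as a separate member, so that pass is not comparable. In that list syt1b, a synaptotagmin gene, rose by 3.64 (adjusted p = 1.44e-05), while the complexin gene cplx3b fell by 1.57 (adjusted p = 0.00139).

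Among 47 genes of neuronal migration, 22 fell and 3 rose (24 and 4 adjusted over the list alone), with a median of -0.38 that ran from -0.4465 to -0.1743 over the settings. The camera adjusted p was 0.0161 with the preset correlation, and the adjusted p with an estimated correlation was 0.706. The gene cdk5r1b, which encodes an activator of the kinase Cdk5, fell by 1.65 with a standard error of 0.23 (adjusted p = 0.000897), and the planar polarity gene vangl2 fell by 2.203 (adjusted p = 0.00929). The chemokine receptor gene cxcr4a rose by 1.62 (adjusted p = 0.00973), with its other probes at 1.714 and, without passing, at 0.6909. The list's median was below 0 on each of the 4 slides, between -0.48 and -0.14. Dynein subunits and LIS1 partners did not shift as a group (camera adjusted p = 0.679), with a median of 0.08, a mean of -0.07, and 3 higher and 6 lower of 27. The dynein heavy chain gene dync1h1 fell by 1.24 with a standard error of 0.21 (adjusted p = 0.00235), with its other probes at -1.40 and -0.30. The probes of ndel1b, a direct LIS1 partner, went opposite ways, at 0.72 (adjusted p = 0.00617) for the brighter and -0.79 (adjusted p = 0.0233 over all probes) for the other.

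Immediate early genes, which are transcribed within minutes of neuronal firing and in other stimulated cells, were lower in the larvae that had been selected for seizures. Of 42 measured, 20 fell and none rose (20 adjusted over the list alone), with a median of -0.50 (camera adjusted p = 0.00225, and adjusted p = 0.706 with an estimated correlation). The gene fosab, the zebrafish c-fos, read 4.08 ± 0.91 in controls and 1.22 ± 0.30 in morphants (SD, n = 4 each), a fall of 2.86 with a standard error of 0.41 (adjusted p = 0.00115). Its other 4 probes changed by -2.97 to -2.57. The neuronal activity-dependent factor gene npas4a fell by 2.03 with a standard error of 0.38 (adjusted p = 0.00391), and its other probe changed by -2.995. Within slides the list's median ran from -0.72 to -0.22.

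The eye lists were lower too. Of 54 phototransduction genes, 31 fell and none rose (33 adjusted over the list alone), 94.4% had a change below 0, and the median was -0.74. Its camera adjusted p was 2.11e-06 with the preset correlation and its adjusted p with an estimated correlation was 0.706. The retinal G protein-coupled receptor gene rgra fell by 2.67 with a standard error of 0.44 (adjusted p = 0.00213), and guca1b, a guanylate cyclase activator gene of photoreceptors, fell by 1.80 with a standard error of 0.43 (adjusted p = 0.0116). Of 53 lens genes, 23 fell and 1 rose (32 and 1 adjusted over the list alone), with a median of -0.47 (camera adjusted p = 4.41e-05, and adjusted p = 0.706 with an estimated correlation). The crystallin genes crygm5 and crygm1 changed by -2.69 and -2.14, and their other probes by -3.72 and -3.38. Medians within slides ran from -1.03 to -0.52 for phototransduction and from -0.81 to -0.15 for lens.

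Erythroid genes and chaperone genes were the lists that were higher. Of 40 erythroid genes, 8 rose and 2 fell (7 and 2 adjusted over the list alone), with a median of 0.60 (camera adjusted p = 0.00225, and adjusted p = 0.706 with an estimated correlation). Of 8 globin genes, 7 had a change above 0, of which 1 passed, while the other 6 were at 0.671 to 1.88 with adjusted p-values of 0.0579 or more. The embryonic globin gene hbbe3 rose by 4.35 with a standard error of 0.45 (adjusted p = 0.000254), whereas the globin gene hbba2 fell by 2.61 (adjusted p = 7.92e-05) and was above background on 1 of 4 morphant arrays. The erythroid median was 0.55 to 1.03 on 3 slides and 0.00145 on slide 4, and fry, which tests whether a list's genes move on balance in a direction, did not call it (adjusted p = 0.138) unless the replicate number was a block (adjusted p = 0.043). Of 51 heat shock and unfolded protein genes, 11 rose and 2 fell (9 and 2 adjusted over the list alone), with a median of 0.16 (camera adjusted p = 0.0219, and adjusted p = 0.706 with an estimated correlation). Within slides that median was 0.0086 on slide 1 and 0.221 to 0.242 on the others. The chaperone gene hspa8b rose by 2.41 with a standard error of 0.21 (adjusted p = 0.000116), and the Hsp90 co-chaperone gene ahsa1b rose by 1.19 (adjusted p = 0.0111). This list was lost without control replicate 3 (adjusted p = 0.0557), without morphant replicate 4 (adjusted p = 0.0858) and with fry (adjusted p = 0.059), though fry with the replicate block called it (adjusted p = 0.0412).

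**Figure D2:**
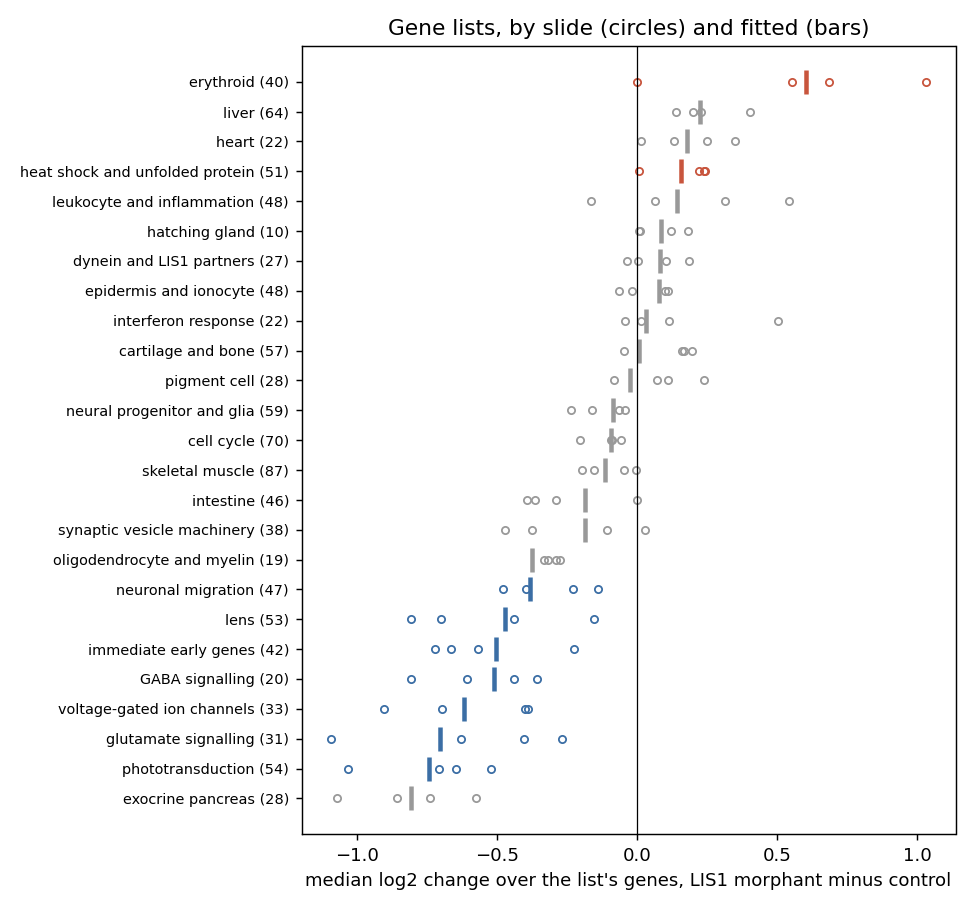
Median log2 change, LIS1 morphant minus control, over the genes of each list reported here, with the number of genes tested in parentheses; circles are the medians within the 4 slides and bars the medians of fitted changes. Blue and red mark the 7 lower and 2 higher lists that passed camera with the preset correlation, such as phototransduction at -0.74 and erythroid at 0.60, and grey marks the rest.

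The other 17 lists did not pass camera with the preset correlation. Neural progenitors and glia had a median of -0.09 (adjusted p = 0.215), oligodendrocytes and myelin -0.37 (adjusted p = 0.323) and the cell cycle -0.09 (adjusted p = 0.385). The interferon response list had a median of 0.03 (adjusted p = 0.654) and the leukocyte list 0.14 (adjusted p = 0.173). Among the lists of other organs, exocrine pancreas had the lowest median, -0.81, with 3 of 28 genes lower, or 1 adjusted over the list alone, and none higher (camera adjusted p = 0.173). With the replicate number as a block it passed at adjusted p = 0.000635, and its adjusted p with an estimated correlation was then 0.664. It also passed without control replicate 4 (median -1.406) and without morphant replicate 1 (median -1.12), while its median was -0.462 without control replicate 1 and -0.42 without morphant replicate 4, where it did not pass. Its elastase gene ela2l fell by 3.67 with a standard error of 0.65 (adjusted p = 0.00308). No list of the 26 passed camera with an estimated correlation, none had an unadjusted p under 0.05 there, and fry called 8, or 15 with the replicate number as a block.

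Some of the genes with large changes were above background in a single group, in either direction. The gene nansb, which encodes a sialic acid synthase, was well above background on all 4 morphant arrays and on none of the controls and was at least 107.9-fold higher in morphants (adjusted p = 3.07e-06). Such bounds were also reached by ms4a17a.1 at 28.4-fold (adjusted p = 5.12e-05), plxnb2a.2 at 10.6-fold (adjusted p = 4.79e-08) and bcan, the gene of the brain matrix protein brevican, at 6.69-fold (adjusted p = 0.000362). The tapasin genes tapbp.1 and tapbp.2, which serve peptide loading of MHC class I molecules, rose by 7.45 and 4.55 on the log2 scale, with 1 and 3 of the 4 control arrays above background. The other probe of tapbp.1 rose by 4.446 and the other probes of tapbp.2 by 2.825 each, so the sizes are uncertain. The fitted rise of the intelectin gene itln3 was 7.36 and that of its other probe 7.56, with 1 of the 4 control arrays above background for the first. Fitted rises of 5.10 and 4.37 were seen in ms4a17a.8 and phyhd1, which were above background on all arrays. For gjc4a.1 and parp14rs1 the fitted rises were 5.01 and 4.63, with 2 and 1 control arrays above background, and for parp14rs1 the difference within slides ran from 1.485 to 6.421, so these sizes are uncertain. The brightest probe of timp2b rose by 4.66, whereas its other probes changed by 0.33 and -1.85 and did not pass.

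Among the falls, nudt5, a nucleotide hydrolase gene, was at least 16.9-fold lower and znf692 at least 21.0-fold lower in morphants (adjusted p = 1.55e-05 and 2.92e-05), with no probe of either above background on any morphant array. A probe of the ubiquitin ligase gene rnf13 was at least 158.4-fold lower (adjusted p = 1.40e-06), but the gene's other probe was above background on all arrays and fell by 0.66. The same disagreement held for the palmitoyltransferase gene zdhhc3b, at -6.87 and -0.38, and for the peptide transporter gene slc15a2, at -6.46 and -1.02. The fatty acid binding protein gene fabp1a fell by 5.91 with a standard error of 0.42 (adjusted p = 3.91e-05), and its other probe changed by -5.86. The fitted changes of dipk1c, rnasel4 and cyp2x9 were -7.58, -7.20 and -6.80, but each was above background on 1 of 4 morphant arrays, so these sizes are uncertain. Those of mep1ba and mpdu1b were -5.42 and -5.41, with 3 of 4 morphant arrays above background, as for slc15a2, and 2 of 4 for fabp1a. The gene c1ql4l, above background on all arrays, fell by 5.41. Of the 371 genes changed by at least 8-fold, 133 were not above background on any array of a group, so their fitted changes carry no measured size on that side. Over all genes with more than 1 probe, the other probes' median went the opposite way for 545 of 3101 called genes.

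**Figure D3:**
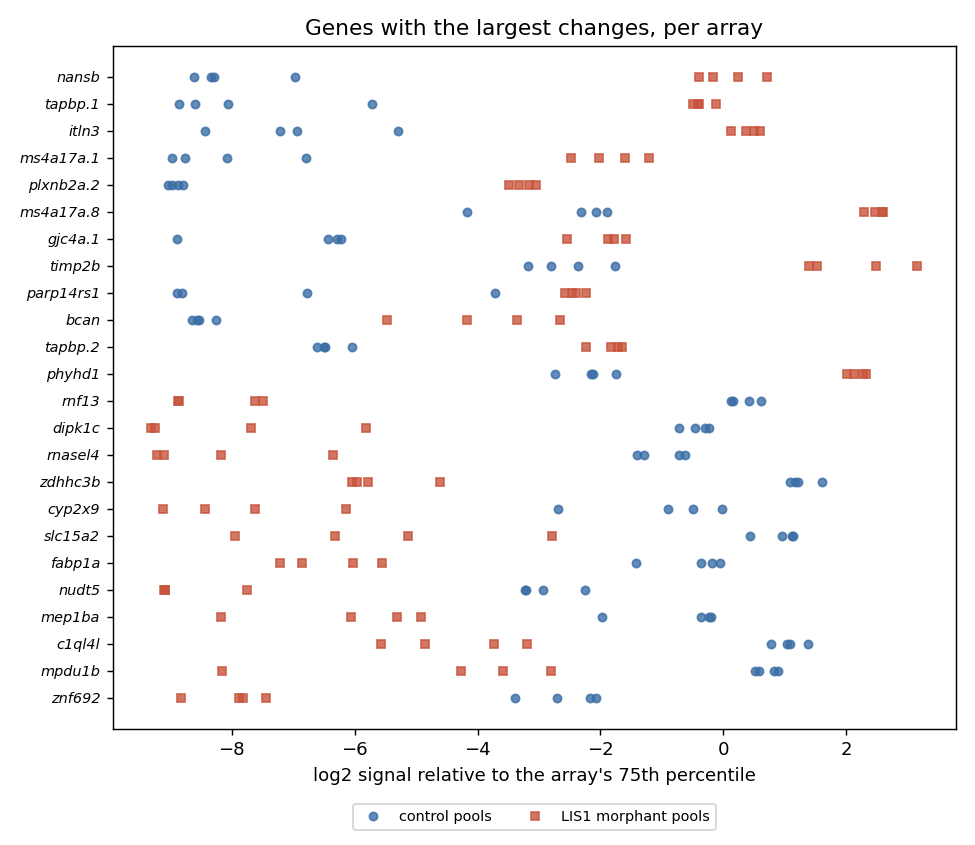
Each point is the log2 signal of a gene's representative probe on an array, relative to the array's 75th percentile, for the 12 named genes with the largest fitted rise (upper rows) and the 12 with the largest fitted fall (lower rows). Control pools (circles) and LIS1 morphant pools (squares) do not overlap in any row, as the rule for naming these genes requires; nansb was at least 107.9-fold higher in morphants.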

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

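In 298 groups of 4 values (named genes, LIS1 probes, array measures and list medians), 19 had a sample set apart from the rest by a gap that took more of the group's whole range than Dixon's 95% critical value for 4 samples allows, where chance gives about 15, or 1 in 20. Values below are log2 levels relative to the array's 75th percentile unless said otherwise, and no explanation was tested for them.

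Pools of replicate 4 recurred for genes of the digestive tract. Control 4 was apart in the meprin gene mep1ba (-1.98 against -0.37 to -0.21, gap 0.911 of the range), the elastase gene ela2l (4.04 against 6.60 to 6.81, gap 0.924), mep1a.2 (0.32 against 1.74 to 1.94, gap 0.879) and the chitinase gene chia.1 (1.52 against 2.94 to 2.96, gap 0.991). Morphant 4 was apart in mep1a.2 (-1.62 against -0.21 to -0.04, gap 0.894) and chia.1 (-0.44 against 1.001 to 1.23, gap 0.861). The intestine list's median level, centred on each gene's mean, was -0.56 in control 4 against 0.32 to 0.34 (gap 0.976), and -0.55 in morphant 4 against 0.03 to 0.10 (gap 0.893). For the liver list it was -0.37 in control 4 against 0.04 to 0.06 (gap 0.939). Control 4 was also low in the erythroid factor gene klf1, at -5.35 against -3.86 to -3.67 (gap 0.89).

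In neural genes, morphant 4 was low in npas4a, at -1.73 against -0.54 to -0.31 (gap 0.836), and in synprb, at -3.31 against -2.73 to -2.64 (gap 0.868). Control 1 was apart in the GABA list's centred median, at 0.11 against 0.34 to 0.37 (gap 0.914), and in the pigment cell list's, at 0.13 against -0.12 to -0.08 (gap 0.844). Of the genes with the largest changes, gjc4a.1 was lower in control 1, at -8.88 against -6.43 to -6.22 (gap 0.918), and nudt5 was higher in morphant 1, at -7.75 against -9.10 to -9.08 (gap 0.984), both near or under the background limit. The muscle gene desmb was higher in morphant 1, at -0.30 against -1.13 to -1.05 (gap 0.904), and the fibrinogen gene fga was lower in control 2, at 1.70 against 1.93 to 1.96 (gap 0.887). The array of morphant 1 had 66 spots marked as outliers against 7 to 14 on the other morphant arrays (gap 0.881).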

How the results depend on the processing

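The alternatives that leave out genes by background or by size of change, and fry with the replicate block, were chosen after seeing the data, and all others before. Of 25 settings for the number of changed genes, 23 gave between 6792 and 11495, within 1.5 times of 8963; with the replicate block it was 10364, of which 8615 were called in both fits. The exceptions were normexp with 75th percentile scaling, with 2735 genes (1413 higher, 1322 lower), and testing every probe, with 14119 (6397 higher, 7722 lower), where more features were tested; for the other the cause was not tested. The share of called genes that were lower, 57.1%, fell below 50% with median scaling (49.57%) and with normexp and 75th percentile scaling (48.34%). Neither LIS1 gene passed in any of 46 values, with changes of -0.267 to 0.36 and a lowest adjusted p of 0.166. These are values of the probe standing for the gene, apart from those of 2 settings. With the mean of probes the second pafah1b1a probe was included, and with every probe tested the least favourable probe was taken. By itself the second pafah1b1a probe passed (0.65, adjusted p = 0.0305 over all probes). With an estimated correlation the number of called lists went from 9 to 0, each at adjusted p = 0.706 with unchanged medians (neuronal migration -0.3817, GABA -0.5099, glutamate -0.7032, ion channels -0.6186, immediate early genes -0.5046, phototransduction -0.7426, lens -0.4719, heat shock 0.1568, erythroid 0.6025). Fry lost the heat shock (median 0.1568) and erythroid (median 0.6025) lists and gained oligodendrocytes (median -0.3734). With the replicate block fry called 15 lists, those of camera and also oligodendrocytes (median -0.3734), cell cycle (median -0.09386), liver (median 0.2247), exocrine pancreas (median -0.8051), intestine (median -0.1859) and epidermis (median 0.07749). Normexp with 75th percentile scaling lost glutamate (median -0.2204) and ion channels (median -0.236) and gained neural progenitors (median -0.09886) and exocrine pancreas (median -0.7708). Exocrine pancreas was also gained with the replicate block (median -0.8051) and with array weights (median -0.9362). Liver was gained without a background filter (median 0.2247), with the filter on all 8 arrays (median 0.2247), with the mean of probes (median 0.4047), with every probe (median 0.4138) and without the genes changed by at least 8-fold (median 0.2363). Testing every probe also gained synaptic vesicles (median -0.3082), oligodendrocytes (median -0.3734) and leukocytes (median 0.2133). In that setting each probe of a gene counted as a separate list member, so the lists it gained, liver included, are not comparable with lists of genes. The random block was not run for the lists, because camera takes no block correlation, and apart from exocrine pancreas and the genes dclk1b and hamp, which it lost (adjusted p = 0.0644 and 0.0722), the replicate block changed no call of a list by camera with the preset correlation and none of a named gene. Leaving out an array in turn gave 6792 to 8909 genes and 9 to 11 lists, with medians of 0.1159 to 0.2244 for heat shock (lost without control 3 or morphant 4), 0.07806 to 0.3163 for liver (gained without control 1, control 3 or morphant 4), -1.406 to -0.42 for exocrine pancreas (gained without control 4 or morphant 1) and -0.3292 to -0.1223 for intestine (gained without control 4).

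Over 113 named genes other than the LIS1 genes, 2337 of 2533 values kept direction and side of the threshold, 179 lost the call and 17 turned direction. With the mean of probes, ndel1b went to -0.03502, gpm6bb to 0.08291 and cldne to 0.4196. Taking the least favourable probe of a gene, timp2b was at -1.85, ndel1b at -0.7904, cacnb4b at -0.9727, cryba1a at -0.5951, gpm6bb at 0.8419, dnaja1 at 0.006716, smyhc1 at 0.1071, myh7l at -0.5035, fhl2b at 1.575 and cldne at 1.094, so the probes of these genes did not all share a direction. For cacnb4b, smyhc1 and myh7l, another probe passed in the reported direction, at 0.5283, -1.069 and 0.9442. Without an array, gpm6bb ranged from -0.7169 to 0.954, because another probe then stood for the gene. Signal over background limits the 313 called genes that were not above background on any array of a group.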

Other observations

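In this part, the tests of a lower share of neurons and of a delay in development were chosen after the result was seen, the condition that the neuron gap also hold on other probes was set after its other p-values were seen, the comparison of gene order with less changed genes was added later, and the limit on the share of genes with a position, which the prediction did not hold, was applied to that test after its p was seen. Genes of other organs moved both ways. Of 57 cartilage and bone genes, 18 rose and 10 fell (18 and 13 adjusted over the list alone), with a median of 0.01 (camera adjusted p = 0.173). The matrix gene ucmab rose by 3.63 (adjusted p = 0.00153) though its other probe was at 0.998 without passing, the parathyroid hormone gene pth1a rose by 3.25 with a standard error of 0.28 (adjusted p = 9.56e-05), and the chondrocyte factor gene sox9a fell by 1.82 (adjusted p = 0.000621) while its other probe changed by -0.5974. Of 64 liver genes, 22 rose and 8 fell, with a median of 0.22 (adjusted p = 0.0685). Without control replicate 4 or morphant replicate 2 that median was 0.07806 or 0.1446, and the list passed without control replicate 1 (0.2276), control replicate 3 (0.2724) or morphant replicate 4 (0.3163) and in further settings, such as the mean of probes (0.4047). The complement factor B gene cfb rose by 1.98 and the fibrinogen gene fga by 1.61 (adjusted p = 0.000942 and 0.000131), though the other probe of fga was at 0.5297 without passing (adjusted p = 0.1705). The complement gene c3b.1 fell by 2.74 (adjusted p = 0.000605).

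Of 87 skeletal muscle genes, 10 rose and 11 fell, with a median of -0.11 (adjusted p = 0.733), and the myoglobin gene mb rose by 1.75 (adjusted p = 0.000603). In that list smyhc1 fell by 2.39 (adjusted p = 0.00326), with its other probes at -1.069 and 0.1071. Of 22 heart genes, 6 rose and 5 fell, with a median of 0.18 and a mean of -0.01 (adjusted p = 0.383). The cardiac factor gene nkx2.5 rose by 1.08 (adjusted p = 0.00115), while tnni4b.3 fell by 2.74 (adjusted p = 1.42e-05). The intestine list had a median of -0.19 (adjusted p = 0.561), with 3 of 46 genes higher and 6 lower. The peptide YY gene pyya rose by 1.32 (adjusted p = 0.000155), and mep1a.2 fell by 1.96 (adjusted p = 0.00991). The epidermis and ionocyte list had a median of 0.08 (adjusted p = 0.234), with 9 of 48 genes higher and 2 lower, and the carbonic anhydrase gene ca15a rose by 1.47 (adjusted p = 5.12e-05). The pigment cell list had a median of -0.03 while its test pointed up (adjusted p = 0.637), and the hatching gland list a median of 0.09 and a mean of -0.03 (adjusted p = 0.679).

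Chance was tested as the source of the 8963 genes called. Of the 35 splits of the 8 arrays into 4 and 4, 1 gave as many genes, the real split. The highest other split called 0 in limma, and no other had over 3985 genes at an unadjusted p under 0.05, against 11306. These 35 splits take all arrays as exchangeable, although the arrays were paired by slide. The 8 splits that part all 4 pairs are too few for a share under 0.05 by themselves (8963 genes in the real split, 0 in the highest other). The real grouping thus stood apart from every other split, but the splits do not exclude chance under the pairing. Stronger array signal in morphants was tested on slide 3, where both arrays had nearly the same 75th percentile (1489.9 and 1491.1). Their median spike-in signals still differed, at 2467.9 on control 3 and 1759.8 on morphant 3. Of 6306 genes called without slide 3, a share of 0.9853 went the same way on it. The 95% interval over genes, 0.982 to 0.9881, takes them as independent although all come from 1 pair of arrays, so it does not cover other slides. The share argues against the difference in 75th percentile as the whole source, but does not address a difference in signal relative to the spike-ins. The morpholino, the selection of affected larvae and injection itself stay open, untested.

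The lower phototransduction, neuronal and immediate early genes were set against 3 explanations. For 126 of the 227 genes with another probe, the other probes had a median change of -0.514 (95% bootstrap interval -0.629 to -0.422), close to the -0.54 of the representative probes, which argues against sequence variants under single probes for these genes. A smaller share of neurons stays open. The median of synaptic vesicle genes lay 0.438 above that of the glutamate, GABA and ion channel genes (two-sided permutation p = 0.00669 over genes, which are not independent replicates). The latter lists were picked because they had fallen, however, and allowing for the pick gave a permutation p = 0.0498. Over the genes' other probes the gap was 0.0998 (permutation p = 0.27). Only 21 synaptic vesicle genes and 32 genes of the other lists had such probes, so that check covers fewer genes. For a delay in development, the median of cell cycle and progenitor genes was -0.0882 (95% bootstrap interval -0.169 to -0.04), with 49 members above 0 and 80 below. That interval lies below 0, which the prediction counted against a delay, but it came from resampling genes, which are not independent replicates. It includes the median of all genes, -0.056, however, a comparison that the prediction did not hold, so a delay stays open too. A change in neuronal and retinal gene activity, as a hypothesis, and larvae collected in different states stay open, untested.

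The genes changed by at least 8-fold in either direction raised the hypothesis that the pools may differ in parental alleles. Of 65 such genes with another probe, a share of 0.215 (95% exact binomial interval 0.123 to 0.335) had a probe that moved by under 1 on the log2 scale, as in rnf13 and zdhhc3b, which leaves variants under single probes open for some genes. The other probes moved by a median of 0.658 of the representative's change (95% bootstrap interval 0.53 to 0.813), which fits a changed transcript in the median gene. For 7 of the 65, however, the other probes went the opposite way. For 918 genes changed 2- to 8-fold with another probe, the median ratio was 0.718. Both intervals treat genes as independent replicates, which they are not. Gene order was taken among tested genes with a position, so genes not tested may lie between neighbours. In that order 6 pairs of such genes were adjacent, related symbols left out, where shuffling gave 1.05 on average (permutation p = 0.00074). Genes changed 2- to 8-fold gave 158 pairs against 149 (permutation p = 0.207). The genes nudt5 and cdc123 are an example, at -5.85 and -5.33, while cfh and cfhl1 are relatives that the rule counted as unrelated. For the genes changed by at least 8-fold, the p meets what was predicted for linked haplotypes. It covers only genes with a position, as the shuffling drew from the 12142 tested genes that had one. Linked haplotypes stay open, since only 116 of the 371 genes (31.3%) had a position, under the limit of 80% applied after the p was seen. The shared pools of eggs given in the design text also speak against separate parents.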
